A study of Homo sapiens with 2 samples.

How the data were processed

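RNA-seq was carried out on 2 cultures of MDA-MB-231 cells, 1 kept in normal medium and 1 given 24 µM D16 for 48 h. Per the labels' protocols, RNA was taken up in TRIzol, libraries were made strand-marked with a uracil-removing enzyme, and paired ends were read on an Illumina NovaSeq instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d, with no role or order, and the genome build is not given in the sources used here. Of the gene identifiers in the table, 58394 were found in GENCODE release 29 on GRCh38; 72.7% had the same start and end there and 99.0% had both ends within 50000 bp. Coordinates are printed as the table gives them.

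The deposited FPKM values, named so per the file headers, were made by the authors and list absent genes at 0.0001, which was read as 0. The deposited estimated counts, also named per the file headers, are whole numbers that follow the FPKM: over 13018 genes with at least 100 counts in each library, 98.4% had the same ratio of treated to control in both units within 1% after 1 common factor of 0.962. How the counts were made is not given in the sources used here. Low counts pile up at multiples of 4, with 473, 1308 and 254 control genes at 3, 4 and 5 counts, so 4 counts were taken as about 1 read pair. This reading was made from the values, and intervals on undivided counts would be narrower. The totals were 72108404 counts in the control library and 73303902 in the treated library.

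The authors' log2 fold changes and p-values come from a deposited table of Gene Ontology terms, and gene names come from a deposited list of top genes, of which 8 columns of per-sample values were not used. A sheet that repeats 7 of the terms and a sheet of numbers without headings were left out.

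The difference of each gene was log2((treated FPKM + 1) / (control FPKM + 1)), which understates the change of low genes, and genes with a mean of at least 1 FPKM in the 2 libraries were counted when at least 2-fold apart. Folds printed beside FPKM values are ratios of FPKM without the pseudocount. Their 95% intervals are exact (Clopper-Pearson) bounds of the share of read pairs in the treated library, turned into a ratio and multiplied by 0.962. Reads are not independent molecules, so these intervals and the floor of 3 read pairs cover counting error only.

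Before the data were examined, 40 gene lists, the tests, the processing alternatives and the rule for named genes were set. A list was described by the median of its members with a mean of at least 1 FPKM and by that median's percentile among 10000 random lists of the same size, drawn within 20 bins of mean expression. Lists with under 5 measured members got no percentile, which left 37. A list beyond percentile 2.5 or 97.5 was called, and about 1.85 of 37 would be called by chance if genes varied independently; genes of a pathway do not, so percentiles describe these libraries and are not p-values. In all, 20 lists were called.

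Named genes were, among genes with a symbol, above 0 in both libraries and with a mean of at least 5 FPKM, the 12 with the largest log2 difference in each direction. For each list, up to 4 members with the largest difference among those with a mean of at least 1 FPKM were named as well. The receptor status genes, the 5 most abundant protein-coding genes of each library and up to 5 genes listed at 0 in 1 library were added, with the authors' first 5 genes in each direction and first 10 terms. Clone-based names were not counted as symbols, a reading settled after the table was seen. TRAF1 and SNAI1 lie outside the rule and were named after their values were seen. Some genes the rule takes are not reported here. The NRF2 gene NFE2L2 is printed under its targets because the rule took it through the aryl hydrocarbon receptor list.

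Genes whose bodies overlap an expressed gene on the same strand were marked, 2866 of 11830, and their counts were also summed with those of the overlapping genes. Alternatives were other pseudocounts of 0.1 and 5 FPKM, other filters and thresholds, rescaled and centred values, counts scaled with edgeR's TMM after rounding, protein-coding genes only, and other ways to draw and summarise lists. Chosen after the data were seen were leaving out overlapping genes, leaving out pseudogenes and small RNAs, summed counts and matching on transcript length. This length was that of each gene's longest transcript in GENCODE, found for 99.6% of the tested genes and used in 5 bins.

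The steps were tested on simulated data drawn from the real means and depths over 11913 genes. For the simulated treated against control comparison, 100% of 50 genes raised 4-fold and 93.9% of 49 genes lowered to 0.333 of their level were found 2-fold apart, as were 0.163% of 11686 unchanged genes. A list raised 1.5-fold lay at percentile 100, and 4% of 200 unchanged lists fell outside 2.5 to 97.5. These figures hold counting error only and none of the variation between cultures. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.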

Results

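RNA from MDA-MB-231 cells, a human triple-negative breast cancer line that carries little estrogen receptor, progesterone receptor or HER2, was sequenced after exposure to D16, a compound the labels call a chalcone, and from cells kept in normal medium. The design held 1 control library and 1 treated library, the latter from cells given 24 µM D16 for 48 h, and the question was which genes differed between them. The deposited counts summed to 72108404 in the control library and 73303902 in the treated library, at about 4 counts per read pair. With 1 library per group no difference below has a replicate check, no p-value was computed, and each 95% interval covers counting error only. "Higher" and "lower" therefore describe these 2 libraries.

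Heme oxygenase 1, ferritin and other antioxidant genes were higher in the treated library, while inflammatory, interferon-stimulated, extracellular matrix and mitochondrially encoded genes were lower. HMOX1, which degrades heme, stood at 4.72 FPKM in the control library and 76.2 FPKM in the treated library, a 16.1-fold difference (95% interval 14.1 to 18.5). FTL, the ferritin light chain, stood at 1455 and 11306 FPKM, and became one of the most abundant protein-coding messages of the treated library. IL6, an inflammatory cytokine, stood at 18.2 and 2.21 FPKM, 8.22-fold lower in the treated library (95% interval 6.65 to 10.2). Among 11830 genes with a mean of at least 1 FPKM, 430 were at least 2-fold higher and 470 at least 2-fold lower on the log2(FPKM + 1) scale. Of these, 345 and 386 were protein-coding, and 8971 of the 11830 genes lay within 1.5-fold.

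The balance between the higher and lower counts depended on scaling. As deposited, 47.8% of the genes past 2-fold were higher. That share was 31.0% (303 higher, 675 lower) after centring on the median of genes with a mean of at least 5 FPKM, which lay at 0.15 on the log2 scale. It was 64.3% (964 higher, 535 lower) after rescaling each library to the same sum of FPKM, which moved the median of all genes by 0.18. Those sums, 336554 in the control library and 296616 in the treated one, include the mitochondrially encoded messages, such as MT-CO2 at 22570 and 11302 FPKM. Their fall therefore raises all other genes under this rescaling. With mitochondrial and the 20 most abundant genes left out of the sums, the share was 41.6% (476 higher, 668 lower). Log2 values below are as deposited, so a list near 0 has no firm direction; where rescaling to equal sums or centring moved a called list's median by more than 1.5 times, that value is given beside it.

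**Figure D1:**
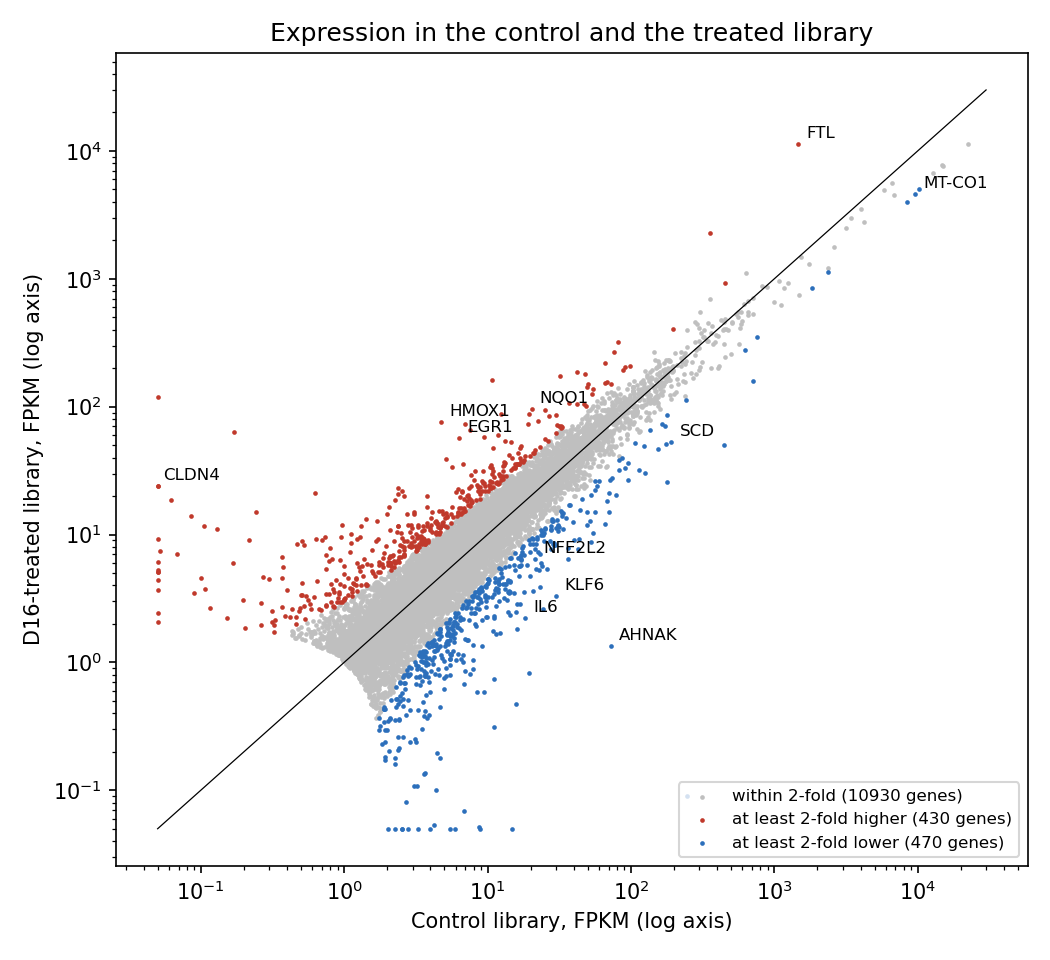
FPKM of 11830 genes in the control library (x axis) and the treated library (y axis), both on log axes, 1 point per gene and 1 library per group, with values under 0.05 FPKM drawn at 0.05 and the line marking equal values. Red points are the 430 genes at least 2-fold higher and blue points the 470 genes at least 2-fold lower on the log2(FPKM + 1) scale; FTL lies above the line at 1455 and 11306 FPKM and AHNAK far below it at 72.4 and 1.34 FPKM.

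Targets of NRF2, the transcription factor that drives antioxidant and detoxification genes, showed the highest median of the 37 gene lists that were set against random lists. All 25 measured members were higher in the treated library, 17 of them at least 2-fold, and the median log2 difference was 1.56, at percentile 100 among 10000 random lists matched on expression. GCLM, a subunit of the enzyme that makes glutathione's precursor, stood at 5.095 and 39.1 FPKM (7.68-fold, 95% interval 7.04 to 8.38). AKR1B10, an aldo-keto reductase, stood at 0.0685 and 7.04 FPKM, a ratio of 103 with a wide interval of 29.7 to 428 because few control reads were seen. NQO1, a quinone reductase, stood at 20.3 and 96.0 FPKM. The message of NRF2 itself, NFE2L2, was lower, at 21.4 and 6.41 FPKM (3.33-fold, 95% interval 3.07 to 3.61).

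Chaperones of the heat shock response were higher as well: all 19 measured members lay above 0, 5 of them by at least 2-fold, with a median of 0.71 at percentile 100. DNAJA1, a cochaperone of HSP70, stood at 91.4 and 206 FPKM, HSPH1 at 12.8 and 28.5 FPKM, and CHORDC1 at 2.52 and 8.14 FPKM. Proteasome subunits differed by less but nearly in unison, with 35 of 37 members above 0, a median of 0.40 (0.26 after centring) and a percentile of 100 after rounding. PSMD12, a subunit of the regulatory particle, stood at 20.8 and 34.9 FPKM. SQSTM1, an autophagy receptor held in this list and in the autophagy list, stood at 50.0 and 150.3 FPKM. The 38 autophagy and lysosome genes had a median of 0.30 at percentile 97.47, just inside the range of random lists, with 6 members at least 2-fold higher, among them the lysosomal enzymes CTSL (54.3 and 136 FPKM) and NEU1 (6.41 and 19.5 FPKM). Replication-dependent histone genes had 14 of 15 measured members above 0, 6 of them by at least 2-fold, and a median of 0.74 at percentile 100. H2BC5 stood at 14.7 and 53.1 FPKM and H4C8 at 1.12 and 10.02 FPKM; most histone messages lack a poly(A) tail, so their level depends on how RNA was selected.

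NF-kB inflammatory genes were lower in the treated library, with 10 of 23 measured members at least 2-fold lower, 1 at least 2-fold higher (TRAF1, 2.22 and 8.85 FPKM), and a median of -0.68 at percentile 0. CXCL1, a neutrophil chemokine, stood at 4.63 and 0.179 FPKM (25.9-fold lower, 95% interval 10.4 to 64.4). The adhesion molecule ICAM1 stood at 25.9 and 5.36 FPKM. Interferon-stimulated genes had 8 of 30 members at least 2-fold lower and none at least 2-fold higher, with a median of -0.57 at percentile 0. IFIT1 stood at 13.2 and 3.77 FPKM and OAS3 at 3.66 and 0.786 FPKM. IFITM1, at 72.0 and 26.5 FPKM, overlaps IFITM2 and came just within 2-fold, at -0.99 on the log2 scale, when summed with it. Antigen presentation genes had a median of -0.25 at percentile 0.94 (-0.14 after rescaling to equal sums, -0.39 after centring), although CD274, which encodes the checkpoint ligand PD-L1, was the list's 1 member at least 2-fold higher, at 2.39 and 20.7 FPKM (8.69-fold, 95% interval 7.50 to 10.04). This list's call was lost when the mean replaced the median (percentile 5.38) and when members overlapping another gene were left out (percentile 4.005).

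Collagen and matrix protein genes were lower in 25 of 26 measured members, 10 of them by at least 2-fold, with a median of -0.93 at percentile 0. TNC, a matrix glycoprotein, stood at 6.79 and 1.01 FPKM (6.70-fold lower, 95% interval 5.79 to 7.77). The laminin chains LAMA5 (9.85 and 2.24 FPKM) and LAMB1 (13.8 and 4.31 FPKM) were lower too. Integrins had 11 of 12 members below 0 and a median of -0.57 at percentile 0.04. ITGB4, a laminin receptor chain, stood at 24.0 and 5.66 FPKM and its partner ITGA6 at 39.1 and 12.6 FPKM. Mesenchymal genes had 6 of 17 members at least 2-fold lower, 1 at least 2-fold higher (SNAI1, 0.924 and 3.40 FPKM) and a median of -0.60 at percentile 0.01, or -0.38 at percentile 2.37 over the 6 members in no other list, with FN1 at 29.9 and 11.2 FPKM, LOX at 11.4 and 3.85 FPKM and CDH11 at 12.1 and 4.07 FPKM. Epithelial genes were lower on the median as well, at -0.63 and percentile 0, although the call was lost with the mean of members (percentile 8.32). KRT19 stood at 177 and 86.7 FPKM and CLDN7 at 17.2 and 6.95 FPKM. CLDN4, a tight junction gene of the same list, went the other way, from 0.0478 to 23.9 FPKM, a ratio of 500.1 (95% interval 203 to 1464).

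Genes of matrix remodelling and invasion had a median of -0.12 at percentile 3.62, with 6 of 22 members at least 2-fold lower, 1 at least 2-fold higher and 10 above 0. The median was 0.009 at percentile 22.8 without overlapping members and -0.04 at percentile 17.2 over members in no other list, while with the mean (-0.34, percentile 0.77) and at a mean of at least 5 FPKM (-0.40, percentile 0.05) the list lay below random lists. The protease CTSL was the higher member, at 54.3 and 136 FPKM. The protease inhibitor TIMP3 stood at 113 and 32.0 FPKM, the plasminogen activator PLAT at 79.3 and 20.2 FPKM, and ADAM8 at 19.9 and 4.77 FPKM. TGF-beta targets lay at percentile 2.03 with a median of -0.17 (-0.02 after rescaling to equal sums, -0.32 after centring); ID2 (0.511 and 4.15 FPKM) and ID3 (6.62 and 21.5 FPKM) were higher, and NOG (14.3 and 4.27 FPKM) and LTBP1 (5.89 and 1.70 FPKM) lower. The call was lost with the mean (percentile 2.70), with members in no other list (percentile 11.7) and without overlapping members (percentile 2.93). YAP and TEAD targets had a median of -0.11 at percentile 4.59, with 13 of 21 members below 0 and ANKRD1 at 410.2 and 208 FPKM.

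**Figure D2:**
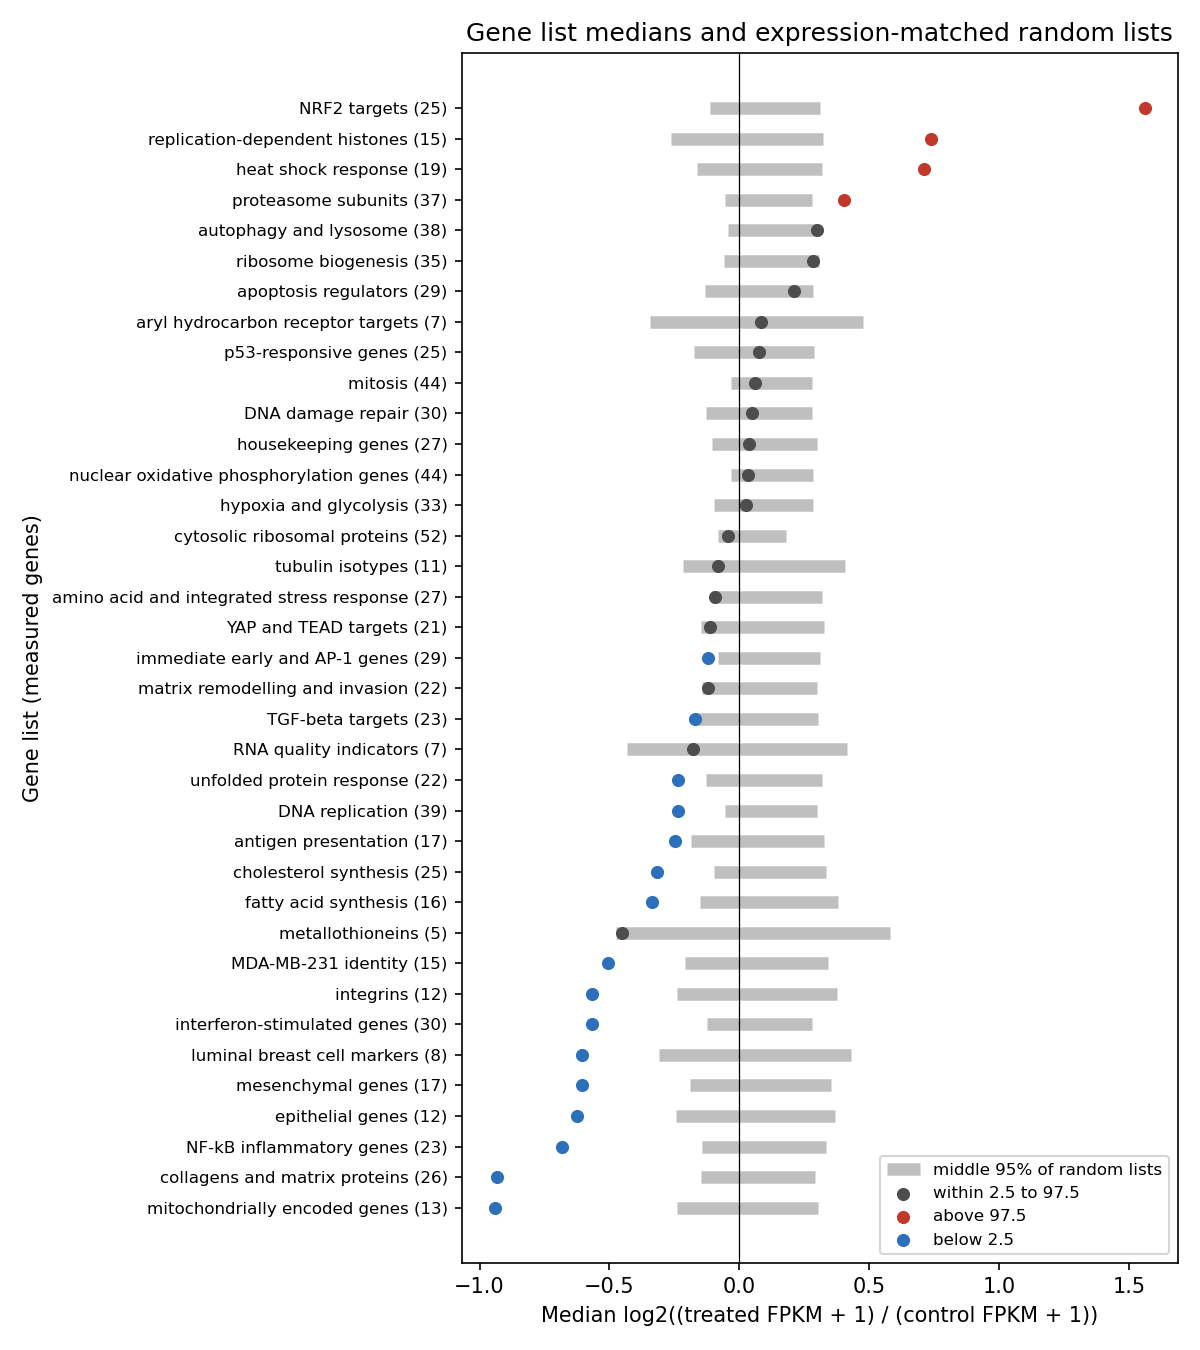
Median log2((treated FPKM + 1) / (control FPKM + 1)) of the 37 gene lists with at least 5 measured members (points; number of measured genes in parentheses), from 1 control and 1 treated library. Grey bars hold the middle 95% of 10000 random lists matched on expression; 4 lists lie above that range (red), led by NRF2 targets at 1.56, and 16 below it (blue), with mitochondrially encoded genes at -0.94.

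Lipid synthesis genes were lower on the median. Cholesterol synthesis genes had a median of -0.32 at percentile 0.02 (-0.15 after rescaling to equal sums), with 3 of 25 members at least 2-fold lower, 1 at least 2-fold higher and 9 above 0. INSIG1, a sterol-sensing regulator, stood at 49.2 and 11.9 FPKM, and the higher member, SC5D, a sterol desaturase, at 4.57 and 10.2 FPKM. Fatty acid synthesis genes had a median of -0.34 at percentile 0.06 (-0.16 after rescaling to equal sums), a call lost without overlapping members (percentile 5.81). SCD, the stearoyl-CoA desaturase, stood at 191 and 52.8 FPKM, the transcription factor SREBF1 at 10.7 and 3.27 FPKM, and FASN at 32.5 and 15.3 FPKM. ME1, which is also an NRF2 target, was higher at 7.69 and 18.5 FPKM.

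All 13 mitochondrially encoded messages were lower, with a median of -0.94 at percentile 0, and they took 11.1% of the control counts and 6.60% of the treated counts. MT-CO3 stood at 8471 and 3983 FPKM and MT-CO1 at 9538 and 4580 FPKM, among the largest differences of the list, while MT-ND1 (5839 and 4964 FPKM), MT-ND2 (6577 and 5626 FPKM) and MT-CYB (3407 and 2995 FPKM) differed by -0.23, -0.23 and -0.19 on the log2 scale. Over the 8 messages that overlap no other gene the median was -0.45, at percentile 0.45. The 5 left out, MT-ATP8, MT-ATP6, MT-CO3, MT-ND4L and MT-ND4, overlap only at their ends and ran from -1.09 to -0.94. All 5 were lower, so reads passing from one to another do not account for their differences. MT-ND4 had a ratio of 0.521 alone and 0.517 when summed. Nuclear genes for oxidative phosphorylation had a median of 0.03 at percentile 10.4, with none of 44 members 2-fold apart. MT-CO2, at 22570 FPKM in the control library and 11302 in the treated one, was among the 5 most abundant protein-coding genes of both.

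Several stress and growth lists showed small or mixed differences. DNA replication genes had a median of -0.24 at percentile 0.01 (-0.08 after rescaling to equal sums, -0.38 after centring) and 28 of 39 members below 0, with MCM6, a helicase subunit, at 18.9 and 5.79 FPKM and LIG1 at 9.02 and 3.91 FPKM. Mitosis genes had a median of 0.06 at percentile 17.8, with TOP2A at 82.6 and 38.4 FPKM and CKS2 at 197 and 404 FPKM. Genes of the unfolded protein response had a median of -0.24 at percentile 0.23 (-0.06 after rescaling to equal sums, -0.38 after centring), with none of 22 members 2-fold apart, and the call was lost with the mean (percentile 7.02); HSPA5, the main chaperone of the endoplasmic reticulum, stood at 571 and 312 FPKM. The amino acid and integrated stress response list lay at -0.09 and percentile 3.02. Its members PPP1R15A (81.6 and 321 FPKM), ATF3 (2.48 and 6.63 FPKM) and SLC3A2 (26.8 and 84.2 FPKM) were higher and DDIT4 (124 and 49.2 FPKM) lower. Immediate early and AP-1 genes had a median of -0.12 at percentile 1.17, but their mean was positive at 0.02 and their median was 0.05 after rescaling to equal sums and -0.27 after centring. EGR1 stood at 6.37 and 57.02 FPKM, 8.95-fold higher (95% interval 8.10 to 9.92), and KLF6 at 30.1 and 3.31 FPKM, 9.10-fold lower (95% interval 8.23 to 10.03).

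Lists on cell death and DNA damage did not stand apart from expression-matched random lists over all measured members, but 2 of them did over part of their members. Apoptosis regulators had a median of 0.21 at percentile 88.0, and of 0.41 at percentile 99.8 over the 23 members in no other list. BCL2L11, which promotes cell death, stood at 0.330 and 2.16 FPKM, BAX, which permeabilises mitochondria, at 20.7 and 43.7 FPKM, the survival gene BCL2L2 at 0.468 and 8.46 FPKM, and the death ligand TNFSF10 at 20.6 and 3.59 FPKM. BCL2L2 overlaps the read-through model BCL2L2-PABPN1, and their summed counts gave a ratio of 13.2. The p53-responsive genes had a median of 0.08 at percentile 50.2, and of 0.59 at percentile 99.9 over the 12 members with a mean of at least 5 FPKM, with 4 of 25 members at least 2-fold higher, among them GADD45A (26.2 and 53.5 FPKM) and GADD45B (9.51 and 25.2 FPKM). DNA damage repair genes lay at 0.05 and percentile 37.8. Tubulin isotypes lay at -0.08 and percentile 12.2, with TUBB2B at 8.70 and 0.0514 FPKM and TUBA4A at 8.85 and 20.9 FPKM. Of the 11 measured isotypes, 7 lay below 0 and 4 above, and TUBB2A was higher, unlike TUBB2B, at 24.4 and 46.2 FPKM. Whether reads were shared between TUBB2A and TUBB2B was not tested. Hypoxia and glycolysis genes lay at 0.02 and percentile 17.8, with ANGPTL4 at 1.302 and 11.7 FPKM and CA12 at 3.62 and 0.382 FPKM. Ribosome biogenesis genes had 32 of 35 members above 0 and a median of 0.28 at percentile 95.2. Cytosolic ribosomal protein genes lay at -0.04 and percentile 5.90, aryl hydrocarbon receptor targets at 0.08 and percentile 49.5, and the 5 measured metallothionein and zinc genes at -0.45 and percentile 2.62.

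Receptor and identity genes were read as a check on the line. ESR1 stood at 0.0192 and 0.00935 FPKM, PGR was at 0 in both libraries, and ERBB2 stood at 5.38 and 5.72 FPKM. EGFR stood at 25.9 and 20.5 FPKM. Among other receptor status genes, FOXA1 stood at 0.0202 and 0.0677 FPKM, ERBB3 at 0.825 and 0.367, GATA3 at 2.43 and 1.25, and TFF1 at 1.93 and 0 FPKM. The 15 genes typical of MDA-MB-231 had a median of -0.50 at percentile 0.01 (-0.32 after rescaling to equal sums), with VIM at 502 and 259 FPKM, PLAU at 135 and 66.2 FPKM and S100A4 at 174 and 71.1 FPKM, a call lost over the 5 members in no other list (percentile 7.11). Of 16 luminal breast cell markers, 8 reached a mean of 1 FPKM, with a highest control value of 177 FPKM, so luminal markers were not absent from these libraries. These 8 had a median of -0.60 at percentile 0.07 (-0.91 with TMM scaling) and a mean of -0.95, with SPDEF at 15.8 and 2.49 FPKM and AGR2 at 16.04 and 2.84 FPKM. Of 13 fibroblast markers 3 reached a mean of 1 FPKM, the most abundant being COL1A1 at 2.72 and 2.46 FPKM, and of 16 blood cell markers 1 did, CD68 at 61.6 and 75.5 FPKM. Housekeeping genes had a median of 0.04 at percentile 19.4, yet POLR2A, the largest subunit of RNA polymerase II, stood at 19.3 and 87.4 FPKM (4.53-fold, 95% interval 4.36 to 4.70). RNA quality indicators had a median of -0.18 at percentile 20.9 over 7 members, 2 of them at least 2-fold lower and 1 at least 2-fold higher. Among these, RNAs without a poly(A) tail went both ways, with RN7SL1 at 8.78 and 3.72 FPKM and RN7SK at 0.486 and 2.52 FPKM, the latter from few reads (5.17-fold, 95% interval 1.43 to 17.6).

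**Figure D3:**
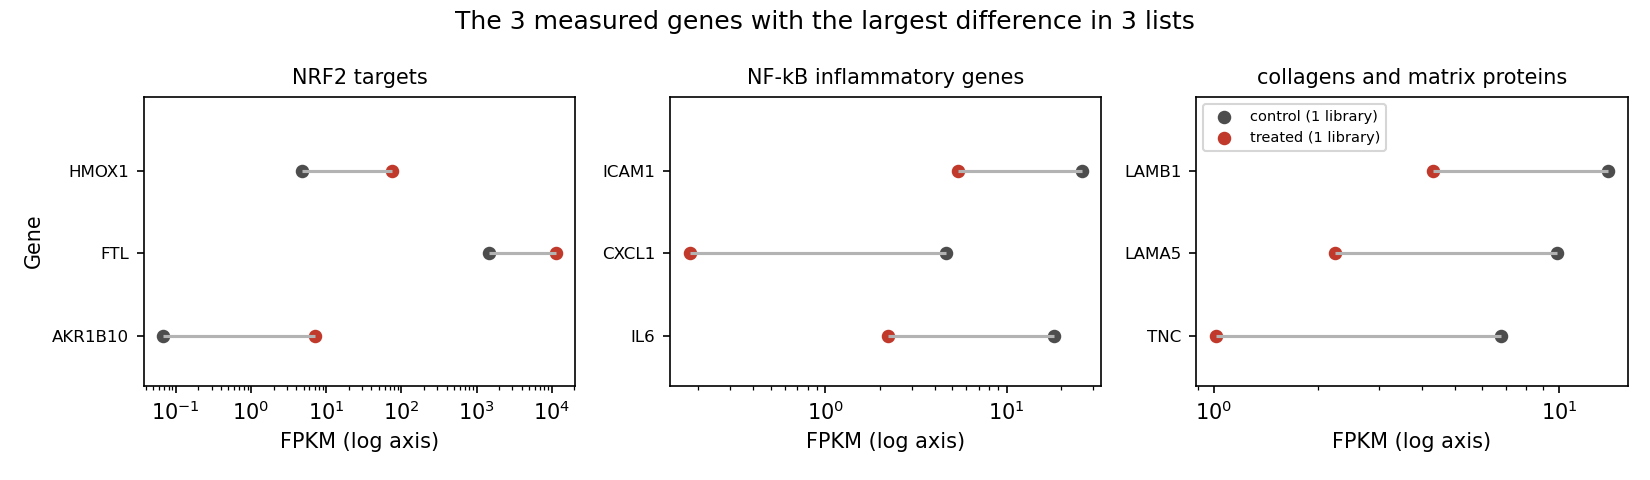
FPKM on log axes of the 3 measured genes with the largest difference in each of 3 lists, with the control library in grey and the treated library in red, 1 library each, so no error bars are drawn. HMOX1 lies at 4.72 and 76.2 FPKM, IL6 at 18.2 and 2.21 FPKM and TNC at 6.79 and 1.01 FPKM.

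The rule for the largest differences also took genes outside these lists. AHNAK (ENSG00000124942), a very large scaffold protein gene on chromosome 11 from 62433542 to 62556235 in the file's coordinates, stood at 72.4 and 1.34 FPKM, 53.9-fold lower (95% interval 49.6 to 58.6). The prion protein gene PRNP stood at 178 and 25.7 FPKM. PNMA2 stood at 11.05 and 0.312 FPKM, the keratin-associated protein gene KRTAP2-3 at 19.5 and 0.823, the epithelial transcription factor EHF at 24.3 and 2.60, the transporter SLCO4A1 at 11.02 and 0.742, and the transcription factor FOXA2 at 15.9 and 1.82 FPKM. The ferritin pseudogenes FTH1P10 (0.630 and 21.3 FPKM), FTH1P7 (6.997 and 73.3 FPKM) and FTH1P11 (7.56 and 66.2 FPKM) share nearly all sequence with FTH1, itself 6.44-fold higher, and are uncertain for that reason.

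Other genes that met the rule lie inside or across another gene on the same strand and are uncertain. EEF1G, a translation elongation factor, was listed at 448 and 50.6 FPKM, 8.86-fold lower, but counts summed with the overlapping gene model gave a ratio of 0.786. PIK3R2 was listed at 15.8 and 0.472 FPKM and its summed ratio was 0.311. UPK3BL1 (0.244 and 14.9 FPKM) and the read-through FAM47E-STBD1 (0.105 and 11.8 FPKM) came within 2-fold when summed. The small RNAs SNORA67, SNORD30, SNORD22, MIR22 and MIR1244-1 lie within longer genes, and their summed ratios were 1.26, 1.62, 1.49, 5.53 and 0.670. Of the genes listed at 0 in 1 library, the 5 highest were read-through models. TMEM189-UBE2V1 was at 0 and 119 FPKM, at least 2313-fold higher against a floor of 3 read pairs, and its locus as a whole had a ratio of 1.75. RPL17-C18orf32, BIVM-ERCC5 and HSPE1-MOB4 were also at 0 in the control library, and SYS1-DBNDD2 in the treated one; their loci had ratios of 1.06, 0.856, 1.13 and 1.09.

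The authors' deposited tables name 100 genes as up and 100 as down. Of the names that match a single row here, all 94 up genes were higher and all 96 down genes lower in FPKM, with folds from 4.11 to 21.2 and from 5.16 to 53.9. Both lists come from the same 2 libraries, so this agreement was bound to occur and is no separate check. CLDN4 (500-fold) and AKR1B10 (103-fold), both with few control reads, rose more than any matched up name but are absent from the up list. CXCL1 is absent from the down list. The first names of the up list in the authors' deposited table were ZNF778, BCL2L2, POMK, CHAMP1 and TGIF2, and those of the down list AHNAK, PNMA2, PIK3R2, AC006064 and CEMIP. BCL2L2, TGIF2, PIK3R2 and AC006064 overlap another expressed gene on the same strand, as do 29 of the 94 up and 26 of the 96 down names. AC006064 stands on more than 1 row, and its counts summed with those of NOP2 gave a ratio of 1.61. Of the matched names, 85 of 94 and 69 of 96 reached a mean of 1 FPKM, and each of these was at least 2-fold apart. The authors' deposited table of Gene Ontology terms lists 15 terms, each with a p-value of 0, whose derivation from 1 library per group is not given in the sources used here. Its first 10 are extracellular matrix organization, collagen-containing extracellular matrix, protein binding, extracellular region, cell surface, focal adhesion, extracellular space, positive regulation of cell migration, cell migration and wound healing. Log2 fold changes are given there for 99 distinct genes, 86 lower and 13 higher, and all 99 equalled the log2 ratio of the deposited FPKM within 0.01.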

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

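Leaving out overlapping genes or small RNAs, summing counts and matching on length were chosen after the data were seen. Counts of genes at least 2-fold higher and lower were 430 and 470. They were 717 and 847 with a pseudocount of 0.1 FPKM, 150 and 139 with 5 FPKM, 280 and 234 at a mean of at least 5 FPKM, 1563 and 1296 at 1.5-fold, 75 and 57 at 4-fold, and 725 and 921 with TMM scaling. Rescaling to equal sums of FPKM gave 964 higher, against 535 lower. The other settings stayed within 1.5 times. Of 20 called lists, 13 kept their call under every one of the 8 alternatives that gave a value. Centring on the median is among the 8, but it subtracts the same value from every gene. It cannot change a percentile and so tests no call. Rescaling to equal sums and TMM scaling were not among the 8. With the mean of members the immediate early list turned positive (0.021), and calls were lost for the unfolded protein response (-0.11), epithelial genes (-0.19), TGF-beta targets (-0.19) and antigen presentation (-0.18). Without overlapping members, TGF-beta targets (-0.17), antigen presentation (-0.22) and fatty acid synthesis (-0.14) lost theirs. Over members in no other list, TGF-beta targets (-0.088) and the 5 remaining MDA-MB-231 genes (-0.27) did, and against unmatched random lists the immediate early list (-0.12) did. Calls were gained by autophagy and lysosome genes under unmatched lists (0.30), the mean (0.40), a pseudocount of 0.1 (0.33), a mean of at least 5 FPKM (0.38) and no overlapping members (0.45). Ribosome biogenesis gained one under unmatched lists (0.28) and the mean (0.36), and metallothioneins with a pseudocount of 0.1 (-0.52). Matrix remodelling did with the mean (-0.34), at 5 FPKM (-0.40) and matched on length (-0.12), as did cytosolic ribosomal proteins matched on length (-0.043). The integrated stress response did at 5 FPKM (-0.13), with members in no other list (-0.16) and matched on length (-0.094), p53-responsive genes at 5 FPKM (0.59) and apoptosis regulators with members in no other list (0.41). The cause of these changes was not tested. Mitochondrially encoded genes kept their call without overlapping members but at -0.45, since the 5 left out ran from -1.09 to -0.94. Matrix remodelling, not called, lay at 0.009 without overlapping members and -0.04 over members in no other list. Of 116 named genes at least 2-fold apart, 1 changed sign, SNORD22 (0.57 when summed with its host gene), and 11 came within 2-fold when summed. Depth limits genes with few read pairs, such as AKR1B10 and CLDN4 in the control library, and no alternative replaces a second culture. No paired analysis was possible because each group has 1 library.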

Other observations

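The groups in this paragraph were chosen after the data were seen. Genes for HLA class II and its chaperone were lower in all 6 measured members, 4 of them by at least 2-fold, with a median of -1.11. HLA-DRA stood at 39.9 FPKM in the control library and 9.02 in the treated one, and CD74 at 37.7 and 17.02. All 4 measured lysyl oxidases, which cross-link collagen, were at least 2-fold lower, with LOXL4 at 52.9 and 8.80 FPKM and LOXL2 at 58.0 and 23.8 FPKM. Of 6 acute-phase and complement genes, all were lower, with a median of -1.45, but 4 of them, SAA1 (36.3 and 6.46 FPKM) included, overlap another gene and are uncertain, and the median of the other 2 was -0.91. Of 5 measured insulin-like growth factor binding proteins 4 were lower, IGFBP4 (708 and 158 FPKM) and IGFBP1 (36.1 and 7.79 FPKM) by at least 2-fold, and IGFBP7 (117 and 137 FPKM) was higher. The median of the 5 was -0.29 at percentile 5.83, inside the range of random lists. Of 345 zinc finger genes with ZNF names, 254 were higher in the treated library, with a median of 0.32, against 0.33 over the 245 that overlap no other gene. Only 13 of the 345 were at least 2-fold higher, and 6 were at least 2-fold lower. The median of all tested genes was 0.08, and centring takes 0.15 off each value.

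Of the tests below, the matching on length and the removal of overlapping members for the matrix list were set before their results were seen, and the others after. None compares cultures, so an effect of D16 and a difference between any 2 cultures stay open throughout.

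Overlapping gene models on the same strand showed opposite differences of at least 2-fold in 17 of 582 pairs, against a median of 6 when values were shuffled among these genes within expression bins. An example is EEF1G against AP002990 on chromosome 11. Summing the counts brought 15 of the 17 pairs within 2-fold, but 64.3% of random pairs of 1 higher and 1 lower gene also did so, so that share alone decides little. The median size of the summed log2 difference was 0.35, against 0.79 for random pairs, at percentile 0.52. The random pairs were not matched on expression, and a pair of unequal genes stays near the ratio of the larger one. This comparison therefore cannot decide by itself. Reads assigned to one or another overlapping model may account for many of these pairs, and 2 pairs stayed past 2-fold. These were PIK3R2 with AC007192, at -1.69 when summed, and C18orf32 with RPL17-C18orf32, at 1.16, although that locus as a whole had a ratio of 1.06.

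Collagen and matrix protein genes were lower in the treated library. Their median transcript length of 7060 bases exceeds the 3301 of all tested genes. A bias against long transcripts is argued against as the whole cause by percentile 0 among random lists matched on expression and length. That matching used 5 bins of the longest annotated transcript, not the one expressed, so it is coarse. Across 10328 genes the Spearman rho of log2 difference and length was -0.07, so longer genes were slightly lower. Overlapping models are argued against by percentile 0 over the 21 members that overlap nothing. A loss of admixed fibroblasts is argued against by the low control levels of 13 fibroblast markers, the highest being COL1A1 at 2.72 FPKM. The largest loss among them, 1.02 FPKM for ACTA2, was below the median loss of 5.84 FPKM over the matrix list. At such control levels no marker could have lost 5.84 FPKM, so comparing the losses adds nothing to this. Of the markers, 3 stand in both lists. That D16 lowered these messages may be kept as a hypothesis, not tested against other cultures.

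Mitochondrially encoded messages were lower in the treated library. A larger share of reads for ferritin, which went from 0.232% to 1.73% of counts, would lower all other genes alike, by 0.02 on the log2 scale. This is argued against as the whole cause by the other 6466 genes with a mean of at least 5 FPKM, whose median was 0.15, above the -0.94 of the 13 messages by 1.09, more than these genes' SD of 0.61. Over the 8 messages that overlap nothing (-0.45) the distance was 0.60, just short of that SD. The 5 left out overlap only at their ends and ran from -1.09 to -0.94, so the shorter distance rests on which messages stay. One uniform loss of mitochondrial RNA during library making stays open. The messages ran from -1.09 (MT-CO3) to -0.19 (MT-CYB), but the SD of their log2 differences, 0.36, lay at percentile 10.75 among random lists matched on expression, so they differed among themselves no more than other genes do. The mitochondrial ribosomal RNAs were lower too, MT-RNR2 at -0.58 and MT-RNR1 at -0.46. The 22 mitochondrial tRNAs went both ways, with a median of -0.07, 5 at least 2-fold higher (MT-TM at 42.0 and 185 FPKM) and 4 at least 2-fold lower (MT-TN at 1832 and 851 FPKM). That goes against a loss shared by all mitochondrial RNA, but members that go both ways do not decide it. Whether such a loss or lower levels in the cells made the difference cannot be told apart with 1 library per group.

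AHNAK overlaps no expressed gene on its strand, yet it lies next to EEF1G on chromosome 11. Its counts were 119095 and 2300, and those of EEF1G 99946 and 11733, while the model AP002990 over EEF1G went from 4726 to 73796. Farther along, MTA2 (27.6 and 39.8 FPKM) and GANAB (123 and 103 FPKM) were within 2-fold, whereas NXF1 (10.5 and 24.0 FPKM) and, on the other strand, SLC3A2 (26.8 and 84.2 FPKM) were more than 2-fold higher. This region was singled out after its values were seen.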
